A study of Mus musculus with 2 samples.

How the data were processed

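The samples were F4/80-positive kidney cells of male mice collected 4 days after acute kidney injury, in 2 libraries, 1 from Cre-negative Atg5-floxed mice and 1 from mice labelled as macrophage Atg5 knockout. Groups were taken from the genotype labels. Per the labels' protocols, polyadenylated RNA was made into TruSeq RNA v2 libraries, and per the series' design text these were sequenced in pairs on an Illumina NovaSeq instrument. Per the submitters' processing notes, reads were filtered with fastp 0.18.0, aligned with HISAT2 and assembled with StringTie 1.3.1. The genome build, the annotation release and the tool that made the counts are not given in the sources used here, so no coordinates are printed.

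The authors' deposited table gives, for each of 22322 genes, an estimated count and an FPKM value per library, together with gene symbols and pathway annotation. The deposited estimated counts are not normalized, and 2773 and 2714 genes have fractional values in the control library and the library labelled knockout, so they were rounded to whole numbers. The FPKM values that the authors deposited are counts scaled by gene length and library depth, and were used as an alternative only. In both libraries 5871 genes were listed at 0. The table holds 22 repeated symbols, of which the row with the highest mean CPM was used in lists, and 16 genes without a symbol.

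Counts were scaled with TMM factors from edgeR 4.0.16 (1.001 and 0.999) in R 4.3.3 and given as CPM, counts scaled to a common library total. Total rounded counts were 21348234 in the control library and 22411826 in the library labelled knockout. A gene was measured with at least 1 CPM and at least 10 counts in at least 1 library, which left 13221 genes. The median log2 ratio of these was 0.00, with quartiles at -0.25 and 0.26. The ratio of a gene is its CPM in the library labelled knockout over that in the control library. Its exact Clopper-Pearson 95% interval was computed from the counts and covers counting error only, because reads without molecular identifiers are not independent molecules and each group has 1 library. A count of 0 stood at a floor of 3 counts, or 0.14 and 0.13 CPM, so such ratios are bounds, which held for 19 called genes.

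With 1 library per group no test between groups is possible. A size rule took its place: a ratio of at least 2-fold in either direction with an interval that excludes 1. It compares these libraries and not the conditions. For 26 gene lists and 15 lists of cell type markers, the median log2 ratio was set against 10000 random lists of the same size, with a fixed seed. These were matched in 20 bins on the log2 of the mean CPM of both libraries. A list stood apart below percentile 2.5 or above 97.5, and lists with fewer than 5 measured genes got no percentile. The random lists drew genes independently and were matched on expression only, not on base composition. A percentile therefore describes these 2 libraries and does not measure an excess over chance. Terms of the authors' annotation with 10 to 300 measured genes were treated alike.

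The lists, the size rule, the rule for named genes and the alternatives other than the trend removals were fixed before the data were examined. Atg5 and Lyz2 were always named. Among genes past the size rule with a mean of at least 5 CPM and a proper symbol, the 10 higher and 10 lower genes with the largest conservative fold, the interval bound nearest 1, were named. Each gene list gave up to 3 members past the size rule with the largest conservative fold, or its 2 most abundant members where none passed, and each marker list its 3 most abundant members. Some genes that this rule takes are not reported here.

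GC content, adenine content and length were taken from the longest GENCODE M21 (GRCm38) transcript of each gene, matched by Ensembl identifier for 99.89% of measured genes. After the named genes were seen, a trend of the log2 ratio was removed as medians of 20 bins with linear interpolation, first on GC content, then on log2 length and, in a further alternative, on adenine content. Beyond the outermost bin medians the trend was held constant. Other alternatives were total-count scaling, DESeq2 1.42.0 median-of-ratios size factors, totals without the 100 most abundant and the mitochondrial genes, FPKM with a pseudocount of 1 or 0.1, other filters, fold thresholds and intervals, means in place of medians, 10 expression bins, and lists without shared members.

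The procedures were tested on simulated data, with Poisson counts for the real genes at the real depths and 200 genes changed by known folds. Of 13021 unchanged genes 11 were called. None of 67 genes changed 1.5-fold passed, while 66 of 67 changed 2.5-fold and 66 of 66 changed 4-fold were called in the right direction. The intervals held the true fold for 95.5% of 13221 genes. Of 200 lists of 20 genes drawn from all measured genes, the 200 changed ones included, 6.5% fell outside the random range. After a 1.25-fold shift 100% of these lists lay above it. The simulated counts differed between libraries by counting error only apart from the set changes, so these rates need not hold for the real libraries. A simulated GC slope with a correlation of 0.87 across 13206 genes was reduced to 0.03. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.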

Results

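The series profiled messenger RNA of macrophages taken from injured kidneys of adult male mice. Kidney cells carrying F4/80, a surface protein of mature mouse macrophages, were collected with magnetic beads 4 days after acute kidney injury, and the labels give 10 mice per group. Both groups carried Atg5 alleles flanked by loxP sites. In 1 group the LysM-Cre allele, which places Cre recombinase in the Lyz2 gene of myeloid cells, was present, and this group is labelled as the macrophage Atg5 knockout. The other group lacked Cre and served as the control. Atg5 encodes a protein of the conjugation system that attaches LC3 to the growing autophagosome. The labels give 1 library per group, and whether it pools the 10 mice is not stated. The control library held 21348234 rounded counts over genes and the library labelled knockout 22411826. With 1 library on each side, no difference below has a replicate check and no p-value is given. The intervals are exact 95% intervals of a ratio of counts and cover counting error only.

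Atg5 itself was examined first. Its gene-level count was 287 in the control library and 472 in the library labelled knockout, or 13.4 and 21.1 CPM, the count scaled to a common library total. The ratio was 1.57 with an interval of 1.35 to 1.82, so Atg5 was higher where the label gives a deletion. A gene-level count also takes reads from exons outside the deleted part and therefore does not check the deletion. Because the deletion could not be checked this way, the second library is called the library labelled knockout throughout. Every direction below is relative to the Cre-negative control library. Lyz2, the lysozyme gene that carries the Cre insertion, stood at 2053 CPM in the control library and 1043 CPM in the library labelled knockout. That is 0.508 of the control level, with an interval of 0.4998 to 0.516. Lyz2 has fractional counts, which may come from reads shared with similar genes, so its level is uncertain to that extent.

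Between the libraries, 980 of 13221 measured genes (7.41%) differed by at least 2-fold with an interval that excluded 1. In the library labelled knockout 443 of them were higher and 537 were lower. The most clearly higher genes included Pdgfrb, the receptor of pericytes and fibroblasts for platelet-derived growth factor, at 11.5 CPM in the control library and 37.4 CPM in the library labelled knockout, a 3.25-fold difference (2.82 to 3.76). Cd248, another mural and stromal cell surface protein, was 3.22-fold higher (2.87 to 3.62). Socs3, an inhibitor of cytokine signalling through STAT3, was 2.70-fold higher (2.55 to 2.86), and the AP-1 gene Jund was 2.75-fold higher (2.62 to 2.89). Ppp2ca, a catalytic subunit of protein phosphatase 2A, stood at 93.0 and 261.3 CPM and was 2.81-fold higher. Crls1, the cardiolipin synthase of mitochondria, was 3.85-fold higher and Rtn4rl1 3.67-fold higher. Zdhhc14 was 3.40-fold higher and Rfxap, a factor that acts at MHC class II promoters, 3.03-fold higher. Pcdhgc3 was 3.02-fold higher, but it shares exons with the rest of its protocadherin cluster and its count is uncertain.

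The most clearly lower genes included Ngp, a granule protein of immature neutrophils, at 17.9 CPM in the control library and 3.13 CPM in the library labelled knockout, a ratio of 0.174 (0.133 to 0.226). The nuclear cyclophilin gene Ppig had a ratio of 0.181 (0.153 to 0.213). Zfp758 stood at 0.199, Ankrd12 at 0.210, Mphosph8 at 0.223 and Ccdc88a, which encodes girdin, at 0.231 of the control level. Olfr46, an olfactory receptor gene with fractional counts that is therefore uncertain, stood at 0.255. Smc4, a condensin subunit, stood at 0.258, Tpr, a nuclear pore component, at 0.275, and Akap9, a centrosomal scaffold, at 0.276.

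**Figure D1:**
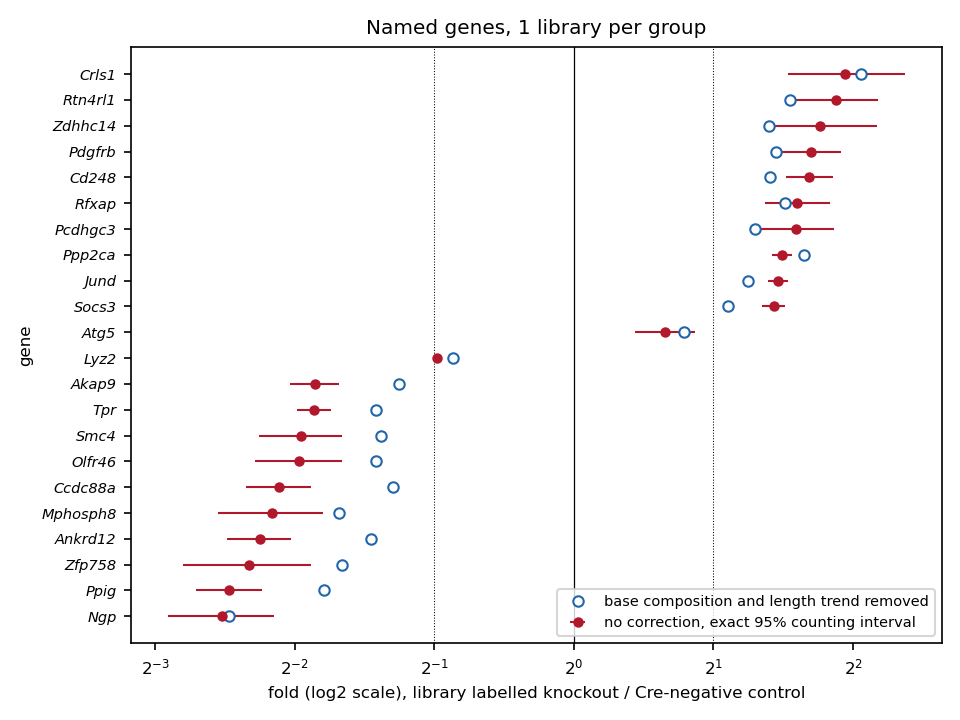
Fold between the libraries (horizontal axis, log2 scale, library labelled knockout over Cre-negative control) for Atg5, Lyz2 and the 10 higher and 10 lower genes named by rule. Filled points carry exact 95% counting intervals, open points have the base composition and length trend removed, and dotted lines mark 2-fold. The open points lie nearer to 1 for most genes, as for Ppig at 0.181 before and 0.289 after, while Ngp stays at 0.174 and 0.180.

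The ratio between the libraries followed the base composition of the transcripts. The Spearman correlation of the log2 ratio with transcript GC content was 0.47 across 13206 genes, which are not independent replicates. In the bin of genes with the least GC, of 10 equal bins, the median log2 ratio was -0.36, with 14 genes higher and 188 lower. In the bin with the most GC it was 0.29, with 127 higher and 17 lower. Of the lower genes with a matched transcript, 47.2% lay in the bin with the most adenine of 10. Of the 10 lower genes named above, Ngp had 25.7% adenine, and the others had between 32.4% (Ppig) and 36.5% (Zfp758), against a median of 25.3% over measured genes. Ratios were therefore also computed after removing the trend on GC content, adenine content and length, called the composition trend below, an alternative chosen after seeing the data. With it removed, 329 genes were higher and 391 lower, of which 285 and 336 were among those counted without the correction. All 20 genes named above passed the same size rule with the trend removed. Several lower ones moved toward 1 by over 1.5 times, Ppig to 0.289, Zfp758 to 0.316, Ankrd12 to 0.366, Ccdc88a to 0.407 and Akap9 to 0.420 of control. The trend was held constant beyond the outermost bins, so for the most adenine-rich of these genes part of it may remain.

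**Figure D2:**
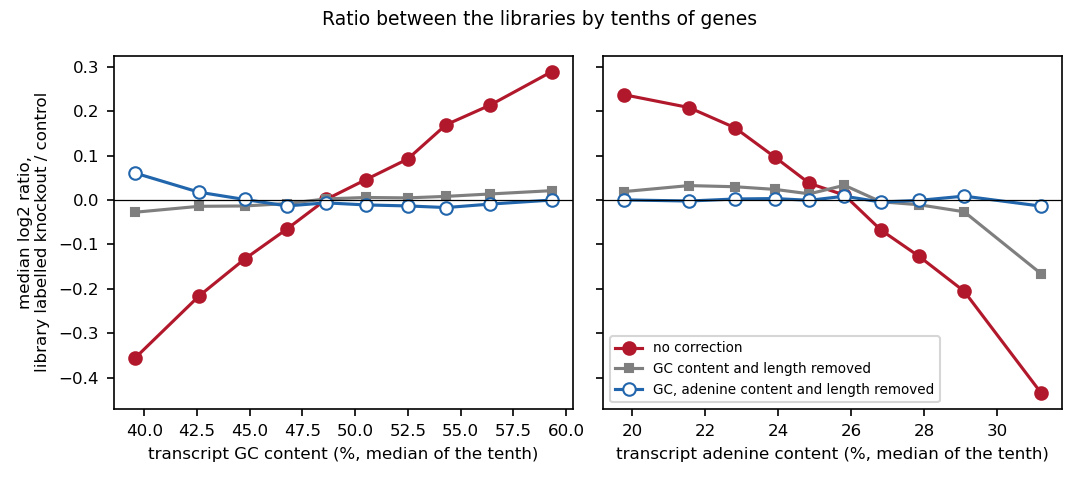
Median log2 ratio (vertical axis, library labelled knockout over control) in 10 equal bins of the 13206 genes ordered by transcript GC content (left, percent) or adenine content (right, percent). Without correction it runs from -0.36 to 0.29 with rising GC content, and in the bin with the most adenine it is -0.43, or -0.17 once GC content and length are removed.

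Genes of macrophage activation mostly had higher levels in the library labelled knockout. Of 25 measured genes of pro-inflammatory activation, 22 had a ratio above 1, and their median was 1.297-fold higher, at percentile 100 of 10000 random lists of matched expression. The random lists were matched on expression only, so percentiles here and below do not measure an excess over chance. Socs3 was the member of the pro-inflammatory list higher by the size rule. It also belongs to the list of immediate early and heat shock genes, which respond to tissue dissociation and were higher too, with a median of 1.39 times control at percentile 100. The chemokine gene Cxcl3 was lower, at 4.59 and 1.92 CPM. Genes of alternative activation had a median of 1.19 times control, at percentile 99.02 over 17 genes. Among them Arg1, which encodes arginase 1, was 2.11-fold higher (1.95 to 2.29) and Il4ra, the receptor chain for interleukin 4 and 13, was 2.03-fold higher (1.91 to 2.16). Il4ra was 1.68-fold higher with the composition trend removed and no longer passed. Ccl24 of the same list was lower, with 24 counts in the control library and 2 in the library labelled knockout. Genes of resident kidney macrophages had a median of 1.20 times control (percentile 99.87, 19 genes), none past the size rule, with Apoe at 1517 and 2144 CPM and Cd81 at 1953 and 2103 CPM. The calls of alternative activation and of resident macrophages were lost when members shared between lists were left out, at percentiles of 91.9 and 68.7, and the former also with a mean in place of the median, at 77.3. General macrophage markers were higher too, with a median of 1.23 times control (percentile 99.91, 13 genes). That is near the medians of several macrophage lists here and below, and some of their members are among these markers. The ratios therefore do not separate a change within macrophages from a larger share of macrophages in the library labelled knockout.

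Genes of infiltrating monocytes lay below the random range, with a median of 0.878 of control at percentile 2.34 over 15 genes, none past the size rule. That call ended with the composition trend removed, where the median was 0.979 of control at percentile 33.7. It also ended with a mean in place of the median, at percentile 17.4, and without shared members, at 5.43. Chil3, a chitinase-like protein of monocytes and alternatively activated cells, stood at 643 and 544 CPM, and Thbs1 at 164 and 170 CPM. Of 16 inflammasome genes none passed the size rule, and their median of 1.11 times control lay at percentile 93.3. It moved to percentile 99.3 with the composition trend removed. Il1b, which encodes interleukin 1 beta, was at 214 and 317 CPM, and Txnip at 361 and 384 CPM.

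Type I interferon response genes were higher as a group in the library labelled knockout. Of 32 measured members 25 had a ratio above 1, 4 were higher by the size rule and none was lower, and the median was 1.31-fold higher at percentile 100. Oas3, an antiviral oligoadenylate synthetase, was 3.35-fold higher (2.47 to 4.61). Oasl1 was 2.71-fold higher (2.27 to 3.24) and Dhx58, a regulator of RNA sensing, 2.14-fold higher (1.80 to 2.55), or 1.88-fold with the composition trend removed. The interferon gamma list did not stand apart, with a median of 1.10 times control at percentile 88.9 over 18 genes. Its member Ido1, an enzyme of tryptophan breakdown, was lower on 27 and 4 counts.

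Antigen presentation genes were higher by small amounts. The 12 MHC class II genes had a median of 1.27 times control at percentile 99.7, and none passed the size rule. Cd74, the invariant chain, stood at 1960 and 3121 CPM, a 1.59-fold difference (1.57 to 1.61). With a mean in place of the median the list's percentile was 97.2, just inside the random range. The 21 MHC class I genes had a median of 1.18 times control at percentile 99.86, with H2-D1, a gene with close paralogs, at 2287 and 3005 CPM and B2m at 2422 and 2523 CPM. None passed the size rule, and with the composition trend removed the list's percentile was 92.4.

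Of 28 chemokine and chemokine receptor genes, 2 were higher and 2 lower by the size rule, and the median was 1.16 times control at percentile 99.7. The monocyte attractant Ccl12 was 2.08-fold higher (1.94 to 2.23), and Ccl24 and Cxcl3 were the lower pair. With a mean in place of the median the list lay at percentile 72.2. Complement genes had a median of 1.23 times control at percentile 99.96 over 16 genes. C2 was 3.14-fold higher (2.31 to 4.33) at 2.57 and 8.08 CPM, and C4b 2.36-fold higher (1.54 to 3.67), or 1.96-fold with the composition trend removed. The complement call was lost, at percentile 97.3, when shared members were left out. Genes of phagocytosis and efferocytosis had a median of 1.22 times control at percentile 99.98 over 22 genes. Axl, a receptor for phosphatidylserine-bound Gas6 on dying cells, was 2.16-fold higher (2.05 to 2.28) and the list's member past the size rule, and was 1.80-fold higher with the composition trend removed.

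Cell cycle genes were lower as a group in the library labelled knockout. Of 30 measured members 29 had a ratio below 1, 11 were lower by the size rule and none was higher, and the median was 0.726 of control at percentile 0 of the random lists. Cenpe, a kinetochore motor, had 57 and 10 counts and a ratio of 0.167 (0.0762 to 0.331). Ccna2, which encodes cyclin A2, stood at 0.232 of control (0.128 to 0.398) and the proliferation marker Mki67 at 0.233 (0.109 to 0.458), at 2.11 and 0.491 CPM. After removal of the composition trend 9 members were lower and the median was 0.663 of control at percentile 0. Neutrophil marker genes were lower beside them, as given below.

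The autophagy machinery showed no shift as a group. Its 30 measured genes, with Atg5 left out, had a median of 1.05 times control at percentile 86.5, and 1 of them passed the size rule. That gene was Rb1cc1, which encodes the FIP200 subunit of the ULK1 complex, at 91.4 and 33.3 CPM and a ratio of 0.364 (0.334 to 0.396). Its ratio was 0.591 with the composition trend removed, and it no longer passed. The 13 autophagy receptor genes had a median of 1.03 times control at percentile 69.6, with Sqstm1, which encodes p62, at 585 and 694 CPM and Tollip at 228 and 252 CPM. Lysosome genes were slightly higher, with 28 of 35 ratios above 1 and a median of 1.15 times control at percentile 99.98. The protease genes Ctsb and Ctss stood at 1.29 and 1.18 times control. The 17 genes of the NRF2 and oxidative stress response had a median of 1.16 times control at percentile 99.7, with the ferritin genes Fth1 and Ftl1 at 1.18 and 1.19 times control. No member of these last 3 lists passed the size rule.

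Genes of fibrosis gave no common direction that held. Of 26 pro-fibrotic macrophage factors 2 were higher by the size rule and none was lower, and the median of 1.04 times control lay at percentile 75.9. Of their ratios 15 lay above 1 and 11 below. Spp1, a member that the naming rule does not take, held 5.923% of all counts in the control library and 4.795% in the library labelled knockout. Mmp2, a gelatinase that cleaves matrix, was 2.67-fold higher (2.27 to 3.16), and Arg1 belongs to this list as well. Extracellular matrix and myofibroblast genes had a median of 1.29 times control at percentile 99.4 over 19 genes, with 1 higher and 1 lower. The higher gene was Col6a3, on 19 and 40 counts, and the lower was Dcn, the proteoglycan decorin, on 60 and 24 counts. The call of this list ended with the composition trend removed, where its median was 1.06 times control at percentile 80.7 and neither gene passed. With a mean in place of the median its percentile was 85.3.

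Of the metabolic lists, no member passed the size rule. The 48 nuclear-encoded genes of oxidative phosphorylation had a median of 1.004 times control at percentile 56.5, with Atp5b at 1344 and 1569 CPM and Atp5a1 at 775 and 870 CPM. The 22 genes of fatty acid oxidation had a median of 1.06 times control at percentile 90.7, with Hadhb at 374 CPM in both libraries and Acadvl at 273 and 315 CPM. The 25 genes of glycolysis and the hypoxia response had a median of 1.09 times control at percentile 97.6, with Pkm at 1325 and 1631 CPM and Eno1 at 1794 and 1954 CPM. Its call was lost under most alternatives, among them total-count scaling, at percentile 97.3, and removal of the composition trend, at percentile 87.2.

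Immediate early and heat shock genes, which respond to tissue dissociation as well as to injury, had the highest median of the gene lists without the correction. It was 1.39 times control at percentile 100 over 22 genes, with 4 higher and none lower by the size rule. These included Jund, Socs3 and Junb, the last 2.06-fold higher (1.99 to 2.13) at 220 and 453 CPM. Removing the composition trend left the median at 1.18 times control, again at percentile 100 but no longer the highest, below those of pro-inflammatory activation and type I interferon genes among others, and Jund and Socs3 still passed. The unfolded protein response list had a median of 0.964 of control at percentile 22.3 over 23 genes, with Hspa5 at 1009 and 867 CPM and Canx at 610 and 424 CPM. The 80 cytosolic ribosomal protein genes had a median of 0.967 of control at percentile 9.33, with Rplp0 at 605 and 638 CPM and Rpl4 at 443 and 387 CPM. The 13 mitochondrially encoded genes, which took 9.76% of control counts and 9.80% of counts in the library labelled knockout, had a median of 0.945 of control at percentile 12.01. With the composition trend removed that median was 1.57 times control at percentile 100. It lay above 1 only after the removal, whose trend was fitted over all measured genes and need not hold for mitochondrially encoded ones. The value is therefore not read as a raised level. The mitochondrially encoded genes mt-Co1 and mt-Cytb stood at 1.10 and 0.966 of control before and 1.48 and 1.57 after. No member of these last 3 lists passed the size rule without the correction.

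**Figure D3:**
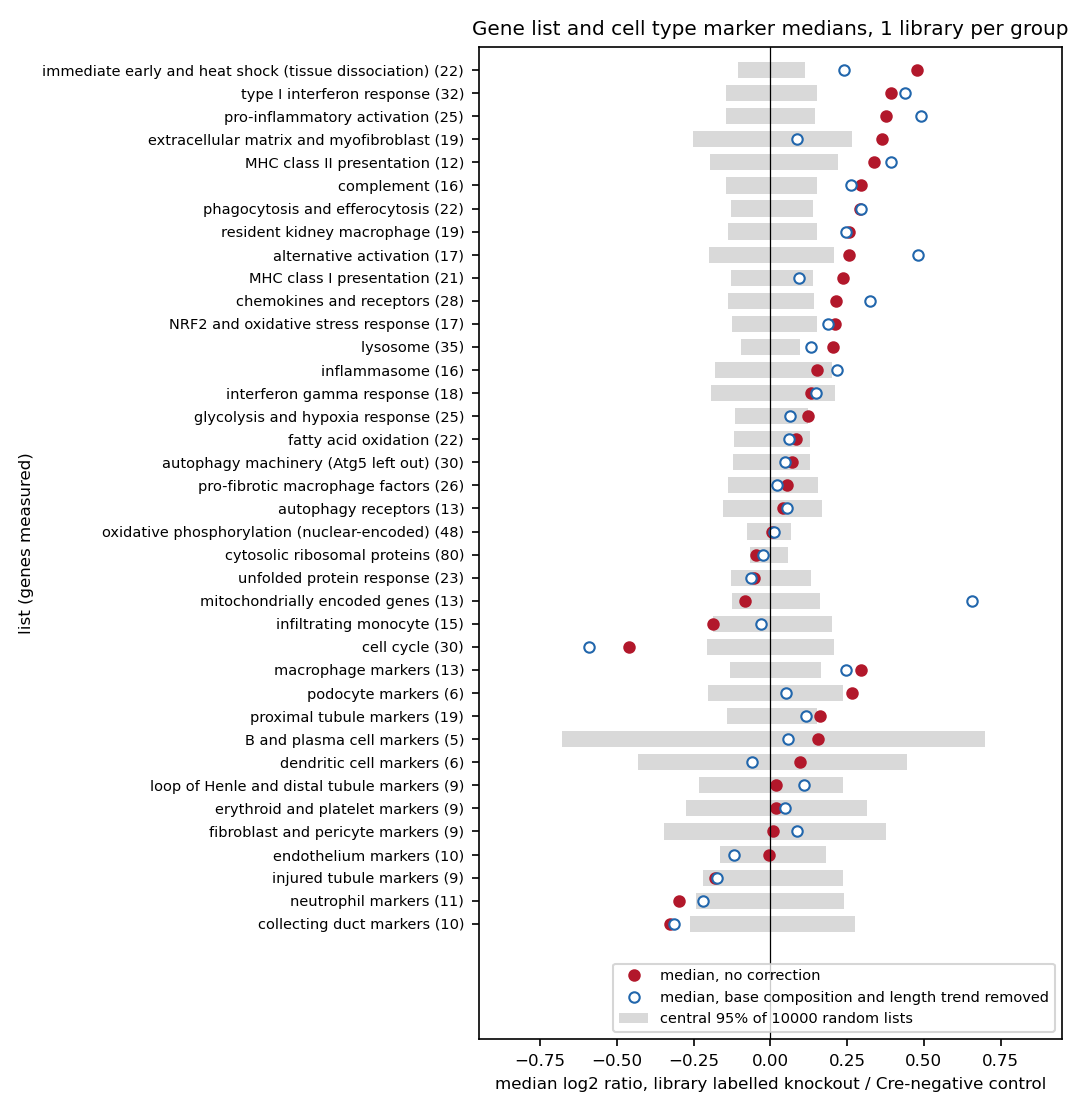
Median log2 ratio (horizontal axis, library labelled knockout over control) of each fixed gene list and cell type marker list with at least 5 measured genes, with that number in parentheses. Filled points are uncorrected, open points have the composition trend removed, and grey bars span the central 95% of 10000 random lists matched on expression, for the uncorrected ratios only. The cell cycle median lies lowest, at -0.46 and -0.59, and the macrophage marker median at 0.30 and 0.25.

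Both libraries held abundant transcripts of other kidney cells after the F4/80 selection. Umod, the uromodulin gene of the thick ascending limb, stood at 2190 and 2282 CPM in the control library and the library labelled knockout. The endothelial gene Kdr was at 1747 and 1878 CPM, near the levels of Ctss among the macrophage markers, at 1771 and 2083 CPM. The macrophage markers Cd14 and Fcer1g stood at 0.931 and 0.984 of control.

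Neutrophil markers were lower in the library labelled knockout, with 10 of 11 ratios below 1, a median of 0.813 of control at percentile 0.815 and 2 genes past the size rule. S100a8 stood at 218 and 150 CPM, S100a9 at 143 and 84.0 CPM, and Il1r2 at 119 and 74.9 CPM. With the trend removed the median was 0.859 of control at percentile 1.59, 1 gene passed the size rule, and S100a9 moved from 0.589 to 0.867 of control. Collecting duct markers were also lower, with a median of 0.798 of control at percentile 0.830 over 10 genes, none past the size rule, Aqp2 at 209 and 206 CPM, Slc26a4 at 55.4 and 44.8 CPM and Atp6v1g3 at 41.7 and 24.6 CPM. The ratio of Atp6v1g3 moved from 0.590 to 0.921 (0.827 to 1.03) with the composition trend removed, while the list stayed below the range at percentile 0.340. Injured tubule markers had a median of 0.883 of control at percentile 4.81 over 9 genes, with Lcn2 at 729 and 537 CPM, Clu at 2305 and 2036 CPM and Krt8 at 334 and 371 CPM. Their percentile was 1.81 with GC content and length removed and 3.03 with the composition trend removed. Proximal tubule markers had a median of 1.12 times control at percentile 97.9 over 19 genes, with Cyp4b1 at 1274 and 1232 CPM and Kap at 409 and 538 CPM. Podocyte markers had a median of 1.20 times control at percentile 98.4 over 6 genes, with Cdkn1c at 1264 and 1269 CPM and Podxl at 856 and 1169 CPM. With the composition trend removed the tubule and podocyte calls ended, at percentiles of 95.8 and 69.0.

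The remaining marker lists did not stand apart without a correction. Endothelial markers had a median of 0.997 of control at percentile 47.9 over 10 genes, which moved to 0.895 at percentile 1.04 with GC content and length removed and to 0.921 at percentile 3.05 with the composition trend removed, with Ehd3 at 1571 and 1541 CPM and Emcn at 1477 and 1084 CPM. Markers of the loop of Henle and distal tubule had a median of 1.01 times control at percentile 59.5 over 9 genes, with Slc12a1 at 1.33 and Kcnj1 at 0.857 of control, and Pvalb, chosen after its values were seen, was the member past the size rule at 0.421 and 1.56 CPM. Fibroblast and pericyte markers had a median of 1.005 times control at percentile 50.4 over 9 genes, of which Pdgfrb was higher and Dcn lower, while Acta2 stood at 1.29 and Rgs5 at 1.005 times control. Dendritic cell markers had a median of 1.07 times control at percentile 69.2 over 6 genes. Zbtb46 stood at 1.05, Fscn1 at 1.20 and Wdfy4 at 1.36 times control, and Clec9a, a gene of cross-presenting dendritic cells chosen after its values were seen, was lower at 9.22 and 3.35 CPM. Markers of B and plasma cells had a median of 1.11 times control at percentile 69.1 over 5 genes, with Ighm at 0.533, Cd79b at 1.12 and Igkc at 1.94 of control, and Jchain, chosen after its values were seen, past the size rule at 0.608 and 1.83 CPM. Erythroid and platelet markers had a median of 1.01 times control at percentile 52.6 over 9 genes, with Hbb-bs at 0.993, Hba-a2 at 1.01 and Hba-a1 at 0.938 of control, genes whose close copies share reads. Of 13 T cell markers 3 were measured, too few for a percentile. Cd4, which macrophages of some tissues also express, was 2.64-fold higher (1.85 to 3.84), and Lck and Tcf7 stood at 1.62 and 1.57 times control. No marker of NK and cytotoxic cells (0 of 9) or of mast cells, basophils and eosinophils (0 of 7) passed the filter on low counts.

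The pathway annotation that the authors' table gives for each gene was described in the same way. Of 326 KEGG terms 95 had a median above the random range and 8 below it, against 16.3 terms for 5% of them. Terms share genes, and the random lists were matched on expression only, so the 5% figure is a reference and does not measure an excess over chance. With the composition trend removed 62 were above, of which 51 were among the 95, and 9 were below, of which 4 were among the 8. Among terms above were antigen processing and presentation (1.18 times control, 57 genes), Jak-STAT signaling (1.13 times, 104 genes), chemokine signaling (1.10 times, 137 genes) and phagosome (1.08 times, 135 genes). ECM-receptor interaction was above as well, at 1.20 times control over 62 genes. Below were cell cycle at 0.915 of control (percentile 0.02, 115 genes), DNA replication at 0.882 (percentile 0.41, 36 genes) and olfactory transduction at 0.755 (46 genes), a term with many near-identical genes whose reads cannot be assigned with confidence. Cell cycle and DNA replication stayed below the range with the composition trend removed, at percentiles of 0.02 and 1.16, but DNA replication did not with only GC content and length removed, at percentile 3.71. Of 2322 gene ontology terms 230 were above and 136 below, against 116.1 for 5% of them. The gene ontology terms were not recomputed with the composition trend removed.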

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

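With 1 library per group no replicate could be left out, and no paired analysis was possible because each group has a single library. The alternatives with the composition trend or the GC content and length trend removed were chosen after the data were seen, and the others before. No called result reversed its direction. With fewer genes tested or a stricter rule, the counts of higher and lower genes moved to 191 and 228 at 5 CPM or more, 54 and 93 at 4-fold, and 126 and 191 with the interval wholly beyond 2-fold. The looser 1.5-fold threshold gave 1260 and 1245. On FPKM they were 91 and 117 with a pseudocount of 1, and 265 and 323 with 0.1. Other scalings, no filter, a wider interval and both trend removals kept the counts within 1.5 times. The log2 ratio of Lyz2 was -0.86 with GC content and length removed and -0.87 with adenine content as well, outside its counting interval.

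These list medians, in log2, lost their call. Glycolysis stood at 0.12 with total counts, 0.13 with median of ratios, 0.10 as a mean, 0.12 at 5 CPM or more, 0.12 without a filter, 0.12 with 10 bins, 0.038 with GC content and length removed and 0.064 with the composition trend removed. As means, alternative activation stood at 0.11, infiltrating monocyte at -0.094, MHC class II at 0.33, chemokines at 0.058 and extracellular matrix at 0.18. Without shared members, alternative activation stood at 0.21, resident macrophage at 0.059, infiltrating monocyte at -0.19 and complement at 0.18. With GC content and length removed, infiltrating monocyte stood at -0.046, MHC class I at 0.12, extracellular matrix at 0.13, proximal tubule at 0.11 and podocyte at 0.065. With the composition trend removed, they stood at -0.031, 0.094, 0.086, 0.12 and 0.051. Annotated pathways above the random range numbered 62 with the composition trend removed. Calls were gained with GC content and length removed by inflammasome, mitochondrially encoded, injured tubule and endothelium genes, and only the first 2 of these also with the composition trend removed. The cause of each loss or gain was not tested. Depth limits low genes such as Cenpe and Mki67, whose intervals span several-fold.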

Other observations

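The genes given here were chosen after their values were seen, and all passed the size rule with the composition trend removed. Ms4a4c belongs to the infiltrating monocyte list, Ifi204 to the type I interferon list, and Il1rn to the alternative activation and inflammasome lists. The others lie outside the fixed lists. With the trend removed Ms4a4c was the 1 member of the monocyte list past the size rule. Without the removal Ms4a4c, Ifi204 and Il1rn did not reach 2-fold, while the others did. Ms4a4c, a gene of the membrane-spanning 4A family, stood at 15.7 CPM in the control library and 28.0 CPM in the library labelled knockout, 2.79-fold higher with the trend removed. The interferon-inducible gene Ifi204 stood at 46.3 and 66.2 CPM, 2.17-fold higher with the trend removed, and Il1rn, the interleukin 1 receptor antagonist, at 52.5 and 91.8 CPM, 2.26-fold higher. Agtr1a, the type 1 angiotensin II receptor, stood at 30.4 and 82.8 CPM and Col12a1 at 8.70 and 23.3 CPM, 2.79-fold and 3.06-fold higher with the trend removed. The fixed list of fibroblast and pericyte markers did not stand apart, at percentile 50.4 without and 71.7 with the removal. Lower with the trend removed were Mmp7, a matrix protease of injured epithelium, at 23.8 and 7.55 CPM, Pglyrp1, a granule protein of neutrophils, at 8.89 and 3.35 CPM, and Uhrf1, a factor of DNA methylation in S phase, at 10.5 and 5.23 CPM.

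The explanations below were tested after the patterns were seen, and the tests with adenine content and those on Lyz2 were chosen after their results were known. The 980 genes past the size rule may come in part from base composition. With GC content and length removed 70.5% of them still passed in the same direction, and 63.4% with adenine content removed as well. Neither the bound of 80% set for excluding this source nor that of 50% set for accepting it was met, so for these genes a technical source and a difference between the mice cannot be told apart with 1 library per group. The lower cell cycle list argues against base composition as its own source, since its percentile was 0.0 with GC content and length bias removed and 0.0 with adenine content bias removed as well. No biological explanation of the lower cell cycle list was tested, and a different mixture of cells stays open, since neutrophil markers were lower too.

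Lyz2 stood at 0.508 of control, or 0.548 (0.540 to 0.557) with the composition trend removed. It carries the Cre insertion, but an effect of the insertion was not tested. A smaller share of macrophages would lower their other markers as well, and these had a median of 1.23 times control. Reads moved to the paralog Lyz1 are also argued against, since the sum of both genes stood at 0.510 of control (0.502 to 0.518). A different mixture of myeloid cells stays open for Lyz2, since neutrophil markers had a median of 0.813 of control. Swapped labels cannot be told apart from correct ones here, because Lyz2 at 0.508 and Atg5 at 1.57 lie on opposite sides of 1 without a replicate. The value of Lyz2 goes with the labels. The gene-level count of Atg5 also takes reads outside the deleted part and does not check them. Reads over the floxed exon were not analysed here.

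Y-linked genes differed between libraries that are both labelled male. Of 7 Y-linked genes 4 had counts, with Ddx3y at 0.528 (0.494 to 0.565), Eif2s3y at 0.622, Uty at 0.752 and Kdm5d at 1.15 (0.961 to 1.38) of control, and a median of 0.684. Cells without a Y chromosome would lower all of them alike, and Kdm5d, 1 gene of 4, was not lowered. Its interval includes 1 and the median lay below 0.8, so the conditions set for excluding this source were not met and it stays open. GC content bias could account for the group, since the median was 0.870 with GC content and length removed, although Ddx3y itself was still at 0.667. Its X-linked homolog Ddx3x stood at 0.633 before removal and 0.733 after. On the X-linked genes read, a small share of XX cells cannot be told apart from none. The 6 X-linked genes that escape inactivation had a median of 0.946 with the trend removed and lay on both sides of 1. Xist, planned as a further check of the sex label, is not reported here.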
